A study of Mus musculus with 15 samples.

How the data were processed

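Whole cortex of adult female mice was profiled on 15 one-colour Agilent microarrays. There were 5 arrays from sedentary SAMR1 mice, 5 from sedentary SAMP8 mice and 5 from exercised SAMP8 mice. SAMP8 is a senescence-prone inbred strain with early memory decline, and SAMR1 is the senescence-resistant strain used as its control. Per the labels' protocols, the tissue was frozen after sacrifice, total RNA was extracted with a column kit, its quality was checked by capillary electrophoresis, and Cy3-labelled cRNA was made by linear amplification. The labels call each array a biological replicate; whether an array held 1 animal or a pool is not given in the sources used here.

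The deposited values were Cy3 spot intensity on a linear scale, 1 column per array. Per the submitters' processing notes, limma was used, with no version or step named. Background correction, normalization, slides, scan dates, detection calls and genome build are not given in the sources used here, so slide and scan could not be tested as batches. The sorted values of the 15 columns were nearly the same: at 99.6% of ranks the columns differed by under 0.05 on the log2 scale. The values were therefore treated as already normalized between arrays. Median intensity was about 208 on each array, the lower quartile lay near 72.1 and the highest value was 65480. No depth exists for arrays, and the number of arrays limits the precision. No detection flags were used; features under the lower quartile are pointed out where a named gene falls there.

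The value table held 45220 features, of which 34479 had values and 10741 were empty on all arrays (5703 of the empty features carry a gene symbol). Of the features with values, 27968 had 1 gene symbol, 38 had several and 6473 had none. The Entrez identifiers of 27891 features were found in the GRCm38.p6 gene table, and 0 symbols needed updating. That assembly was used only for names and for which genes neighbour each other. Values were taken as log2 with no pseudocount, since no value was 0 or less. Each gene was represented by its feature with the highest mean over all arrays, which gave 16401 genes, 6970 of them with more than 1 feature. Features of 1 gene can differ in size; where the other features of a gene had the opposite sign in the comparison it is named for, their median is given beside it.

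Each gene was fitted with limma (version 3.58.1 in R 4.3.3, lmFit and eBayes) over all 15 arrays in 3 groups that share 1 estimate of the spread. Tests were two-sided, with Benjamini-Hochberg adjustment over the 16401 genes and a threshold of 0.05 on adjusted p. The median standard error of a difference was 0.121 on the log2 scale. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Standard errors of log2 differences are limma's. A list's score on an array is the mean over its genes of the log2 value minus the gene's mean over all arrays, and its standard error comes from the same 3-group model.

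Gene lists were fixed from the design alone. There were 37, with 974 entries, 882 of them measured, covering cell types of the cortex and its borders, neighbouring brain regions, synaptic and activity genes, metabolism, protein quality control, immunity, ageing and growth. Each list was tested with limma's camera at its preset correlation of 0.01, adjusted over 111 tests (37 lists in 3 comparisons). Camera with an estimated correlation and fry were run beside it, and each list's score was compared by an exact permutation test, whose smallest p for 5 against 5 arrays is 0.00794. Members were counted over all genes and adjusted over the list alone.

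Genes were named by a rule. In each comparison these were the 12 largest rises and the 12 largest falls among genes that passed and had a symbol that is not a clone or predicted-gene name, plus up to 3 members of each list with the smallest p. Where fewer than 10 genes passed, the 10 with the smallest p were given as values. Comparisons that share arrays were set beside simulated groups with no effect and beside values from the shared arrays split into parts of 2 and 3 arrays.

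The steps were tested on simulated data with 200 of 16401 genes changed. For sedentary SAMP8 against SAMR1, 2% of changes of 0.25, 44% of 0.5, 84% of 1 and 100% of 2 on the log2 scale were recovered, with 1 call among unchanged genes. For exercised against sedentary SAMP8 the shares were 4%, 50%, 84% and 98%, with 8 such calls. For exercised SAMP8 against SAMR1 they were 4%, 54%, 82% and 96%, with 6 such calls. A list of 26 genes moved by 0.3 in the exercise comparison was found by camera at adjusted p = 1.45e-07, and 0 other lists passed. A covariance of -0.0457 put into the simulated strain and exercise effects was recovered as -0.0460. In these simulations each gene varied independently of the others. On the real arrays, genes of 1 list are correlated (estimated at 0.37 for activity-induced genes, the list moved here). The simulations thus do not show how often camera calls unchanged lists, or how exact the covariance is, when genes are correlated.

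The alternatives tried were quantile normalization, centring on each array's median, leaving out the dimmest 30% of genes, the mean of all features of a gene, all features with no collapse to genes, array weights, a trended and robust prior, only the 2 groups compared, an adjusted p of 0.01, a log2 difference of at least 0.5, other list tests and leaving out each array in turn. After the data were seen, 2 more were added: list scores as covariates, and the 2 arrays of lowest weight left out together.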

Results

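Cortical gene expression was measured on 15 arrays from female mice, 5 each from sedentary SAMR1, sedentary SAMP8 and exercised SAMP8 animals. Replicates were numbered 1 to 5 in SAMR1, 6 to 10 in sedentary SAMP8 and 11 to 15 in exercised SAMP8. Correlations between pairs of arrays ran from 0.976 to 0.991 over the 16401 genes, and 0 pairs were identical. The first principal component held 18.2% of the variance and separated all SAMR1 arrays from all SAMP8 arrays, while components 2 (14.6%) and 3 (10.9%) separated neither strain nor exercise. There was no exercised SAMR1 group, so an exercise effect could be measured in SAMP8 only. If arrays held pooled or repeated material, which the labels do not settle, the p-values would measure only the spread between these samples.

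The first comparison asked how the cortex of sedentary SAMP8 mice differed from that of sedentary SAMR1 mice. Ccl19, a chemokine that guides lymphocytes and dendritic cells through the receptor Ccr7, showed the largest rise: its log2 intensity was 8.77 ± 0.20 in SAMR1 and 14.98 ± 0.08 in SAMP8 (mean ± SD, n = 5 each), a 74.5-fold difference (log2 6.22 ± 0.11 SE, limma adjusted p = 9.34e-15). Adat2, a subunit of the tRNA adenosine deaminase, rose by 2.45 ± 0.07 (limma adjusted p = 2.3e-12). Slc2a5, a fructose transporter found in microglia, rose by 1.97 ± 0.10 (1.46e-08), and Fbll1, a fibrillarin-like protein, by 1.93 ± 0.09. Gdpd5, a glycerophosphodiester phosphodiesterase, was 13.1-fold lower in SAMP8 (log2 -3.71 ± 0.13, limma adjusted p = 5.88e-11). Ppp1r1a, an inhibitor of protein phosphatase 1, fell by 2.61 ± 0.10 (2.05e-10), and its other feature gave -2.51.

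**Figure D1:**
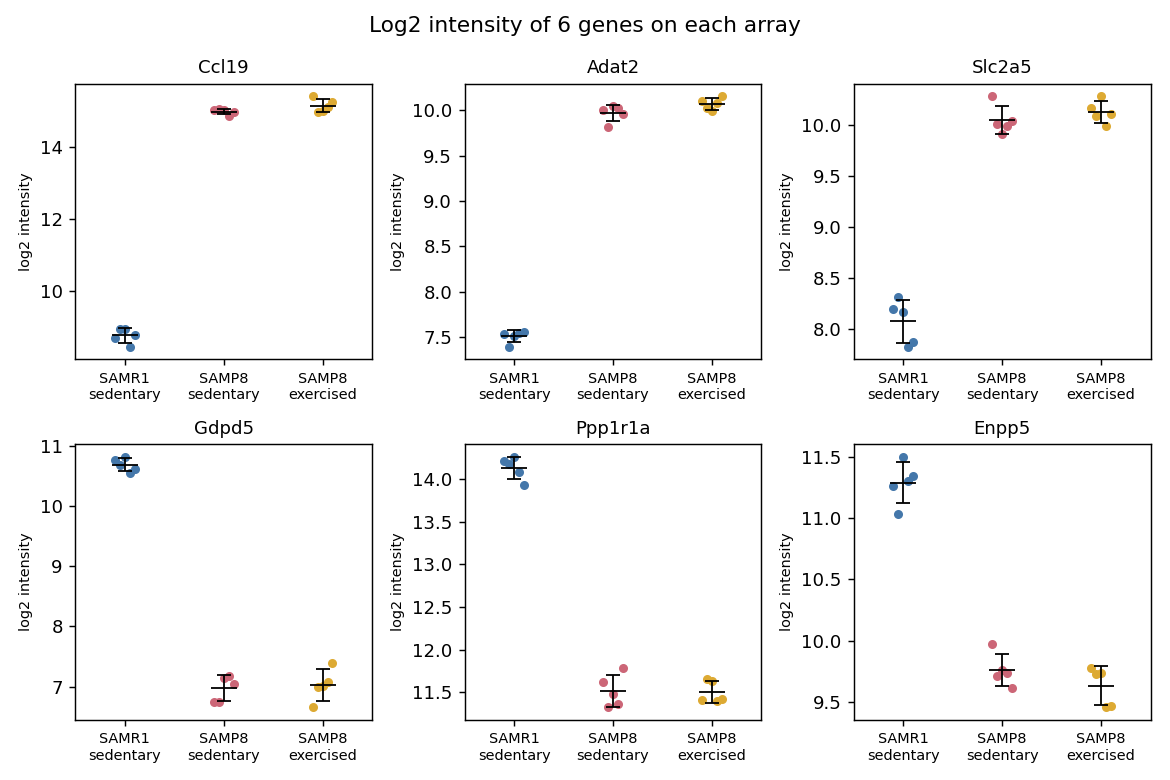
Log2 intensity per array (vertical axis) of Ccl19, Adat2, Slc2a5, Gdpd5, Ppp1r1a and Enpp5 in sedentary SAMR1, sedentary SAMP8 and exercised SAMP8 mice (5 arrays each), with points for arrays and bars for mean ± SD. All SAMP8 arrays lie above all SAMR1 arrays for Ccl19 (14.86 or more against 8.95 or less), Adat2 and Slc2a5, and below them for Gdpd5 (7.40 or less against 10.56 or more), Ppp1r1a and Enpp5.

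In all, 497 of 16401 genes passed in limma, 303 higher and 194 lower in SAMP8 (253 and 207 with quantile normalization, 277 and 203 with median centring), with a median absolute log2 difference of 0.65; 99 were past 2-fold. At an unadjusted p under 0.05 there were 2345 genes, where chance gives 820. In 433 of the 497 genes the 5 SAMP8 values and the 5 SAMR1 values did not overlap. The 497 were selected on these same arrays, so that count is no separate evidence. Over all genes the share was 4.57%, where chance gives 0.794%. Other large rises were in Tmem40, a transmembrane protein (3.56 ± 0.24), H2-Bl, an MHC class I gene (3.05 ± 0.22), Trim12a, of the TRIM family of ubiquitin ligases (2.66 ± 0.09), and Dct, the melanin enzyme dopachrome tautomerase (1.92 ± 0.12). In SAMR1, H2-Bl and Trim12a lay under the lower quartile of intensity on all 5 arrays and Tmem40 on 4 of 5, so the sizes of these 3 rises rest on dim values near an unknown floor. The mean of all features gave 1.86 for H2-Bl. Large falls were seen in Deptor, an inhibitor of mTOR (-2.76 ± 0.15), Prdm16, a transcriptional regulator (-2.73 ± 0.15), Trub1, a pseudouridine synthase (-1.76 ± 0.11), Enpp5, a nucleotide pyrophosphatase family member (-1.53 ± 0.10), and Usf1, a helix-loop-helix transcription factor (-1.41 ± 0.15). Prdm16 lay under the lower quartile on 2 of 5 sedentary SAMP8 arrays. The second Deptor feature gave -0.12, and the mean of all features was -1.44 for Deptor and -0.98 for Trub1. Ccl19, H2-Bl and Trim12a belong to families of near-identical copies, which a feature may not tell apart.

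Interferon and antigen presentation genes had a mean difference of 0.27 ± 0.089 in SAMP8 (camera adjusted p = 0.000566, and adjusted p = 0.810 with an estimated correlation). Of the list, 7 of 31 members rose, 0 fell and 24 did not pass, and 13 rose and 1 fell when adjusted over the list alone. Among them were Oasl2 (1.02 ± 0.13, limma adjusted p = 0.000185) and Oas1a (0.64 ± 0.11, 0.00379), of the oligoadenylate synthetase family of antiviral proteins, and Ifi27l2a, an interferon-induced gene (1.69 ± 0.30, 0.00404). In SAMR1, Oas1a lay under the lower quartile of intensity on 3 of 5 arrays and Ifi27l2a on 1. Meningeal markers moved with it, at a mean of 0.38 ± 0.11 (camera adjusted p = 2.18e-05, and adjusted p = 0.810 with an estimated correlation). Of these 18 genes only Lum, an extracellular matrix proteoglycan, passed over all genes (0.70 ± 0.14, limma adjusted p = 0.0114), and 8 rose and 0 fell when adjusted over the list alone. Choroid plexus markers were all 13 positive, with a mean of 0.68 ± 0.35 (camera adjusted p = 0.00560, 0.0594 without the dimmest 30% of genes, and adjusted p = 0.810 with an estimated correlation). Their 1 member that passed, also when adjusted over the list alone, was the water channel Aqp1 (1.01 ± 0.25, limma adjusted p = 0.0388), under the lower quartile on 3 of 5 SAMR1 arrays. Aqp1 did not pass without SAMR1 replicate 2, 3 or 5, sedentary SAMP8 replicate 6, 7, 8 or 9, or exercised replicate 13 (0.83 to 1.04, adjusted p 0.0519 to 0.103).

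The heat shock and unfolded protein response list was positive in 25 of 26 genes, with 0 passing singly over all genes or adjusted over the list alone. Atf6, a sensor of endoplasmic reticulum stress (0.28 ± 0.11, limma adjusted p = 0.244, other feature -0.05), and Pdia6, a protein disulfide isomerase (0.35 ± 0.15, 0.292), were among the 3 members with the smallest p and lay above the list's median of 0.18. The mean of the list was 0.20 ± 0.063 (camera adjusted p = 0.00223, and adjusted p = 0.810 with an estimated correlation). The insulin and mTOR list was lower, at -0.14 ± 0.031 (camera adjusted p = 0.0219, -0.092 and 0.0772 with the mean of all features, and adjusted p = 0.810 with an estimated correlation). In it 1 of 18 genes fell, also when adjusted over the list alone: Eif4ebp1, a translation repressor controlled by mTOR (-0.79 ± 0.11, limma adjusted p = 0.000454), whose other feature gave -0.30. Activity-induced genes had a mean of 0.46 ± 0.28 over 26 genes, of which 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.0326, and adjusted p = 0.810 with an estimated correlation). Their scores ran from -0.96 to 0.57 over the 5 SAMR1 arrays, against 0.23 ± 0.077 in sedentary SAMP8 (mean ± SD, n = 5). The call on that list was lost without SAMR1 replicate 3 (0.28, adjusted p = 0.318), 4 (0.31, 0.231) or 5 (0.41, 0.0643), or SAMP8 replicate 7 (0.43, 0.0628) or 10 (0.46, 0.0582).

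Lists with no shift as a whole also held genes that changed. Of 26 inflammatory genes, Serpina3n, a protease inhibitor of reactive astrocytes, rose by 0.84 ± 0.11 (limma adjusted p = 0.000256), while the complement gene C4b fell by 1.08 ± 0.15 (0.000401); the list's mean was 0.052 (camera adjusted p = 0.576), with 2 rising and 1 falling when adjusted over the list alone. Gfap, the astrocyte intermediate filament, rose by 0.72 ± 0.14 (0.00771), while the 17 astrocyte markers had a mean of 0.062 (camera adjusted p = 0.857; 2 rose, over all genes and adjusted over the list alone). Gstm2, a glutathione transferase, rose by 0.92 ± 0.10 (4.29e-05) among 29 antioxidant genes with a mean of 0.085 (camera adjusted p = 0.455; 2 rose and 1 fell, over all genes and adjusted over the list alone). Chrna4, a nicotinic acetylcholine receptor subunit, gave 1.18 ± 0.09 on its brighter feature and -1.16 on the other, and 0.01 (limma adjusted p = 0.982) as their mean. C4b and Gstm2 have close paralogs.

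Fry passed 0 lists in each of the 3 comparisons, and so did camera with an estimated correlation. In the exact permutation test of list scores 0 lists passed after adjustment as well (smallest adjusted p = 0.196). Between the sedentary strains its unadjusted p was 0.0159 for the interferon, meningeal, heat shock and insulin lists. For the choroid plexus and activity-induced lists it was 0.0873 and 0.183. With the scores of the striatal, choroid plexus and meningeal lists as covariates, an alternative chosen after the data were seen, 139 genes passed between the strains, 133 of them among the 497. Of the genes named for this comparison, Oasl2 (0.81, adjusted p = 0.0574), Oas1a (0.66, 0.164), Ifi27l2a (0.91, 0.270), Lum (0.25, 0.745), Aqp1 (0.76, 0.513) and Gfap (0.59, 0.296) then did not pass in limma, and Gstm2 passed at 0.60 (0.0180). Of these lost genes, only Oas1a did not shrink (0.64 without the covariates). Without them Oasl2 had 1.02, Ifi27l2a 1.69 and Lum 0.70, and Aqp1 and Gfap shrank too. A call lost with the covariates thus need not mean a smaller difference, though for most of these genes it was smaller. Lum is itself in the meningeal score and Aqp1 in the choroid plexus score. Each was adjusted for a mean that holds its own value, so part of its loss can be built in.

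The second comparison asked what exercise changed in the SAMP8 cortex. In limma 0 of 16401 genes passed between exercised and sedentary SAMP8 (5 arrays each), with a smallest adjusted p of 0.521. At an unadjusted p under 0.05 there were 1162 genes, where chance gives 820 on average. Genes are correlated and the spread of the chance number was not computed, so this count alone shows no exercise effect. The genes with the smallest p were Prpf19, a splicing factor and ubiquitin ligase (-0.95 ± 0.18), Mettl7a1, a methyltransferase-like protein (-0.82 ± 0.16), Zfp644, a zinc finger protein (-0.73 ± 0.16), Ube4a, a ubiquitin ligase (-0.89 ± 0.20), Wwtr1, the Hippo pathway coactivator TAZ (-0.75 ± 0.17), and Rragd, a GTPase of amino acid sensing (-0.58 ± 0.13). On the positive side stood Dcaf12l1 (0.31 ± 0.07), Haspin, a mitotic kinase (0.66 ± 0.15, under the lower quartile of intensity on all 5 sedentary arrays), and Lrrc46 (0.61 ± 0.14, under the lower quartile on 2 of 5 sedentary arrays). Olfr362, an olfactory receptor gene under the lower quartile on all 5 sedentary arrays, gave -0.73 ± 0.16. All of these had a limma adjusted p of 0.521. The other features of Mettl7a1 (0.23), Zfp644 (median 0.07) and Ube4a (median 0.09) had the opposite sign. With array weights, or with a trended and robust prior, 0 genes passed as well. Without exercised replicate 12, 3 genes passed in limma, each at adjusted p = 0.0228: Prpf19 (-1.11), the flow-responsive transcription factor Klf2 (-0.78, against -0.61 over all arrays, on a feature near the scanner ceiling, and -0.42 on the other feature over all arrays) and Lsm14b, an RNA-granule protein chosen after its values were seen (-0.75).

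Striatal markers were the list with the smallest p after exercise. Their mean was -0.37 ± 0.14 (camera adjusted p = 2.87e-08, and adjusted p = 0.810 with an estimated correlation), and 15 of 16 genes were negative. The list's scores were 0.20 ± 0.14 in sedentary and -0.17 ± 0.25 in exercised SAMP8, against -0.028 ± 0.26 in SAMR1 (mean ± SD, n = 5 each); the exact two-sided permutation p was 0.0238, and 0.203 after adjustment over the lists. None of the 16 genes passed singly, and 0 passed when adjusted over the list alone. The phosphodiesterase Pde10a had -0.83 ± 0.25 (limma adjusted p = 0.580, other feature 0.17), the G protein subunit Gng7 -0.53 ± 0.17 (0.590) and Rgs9, a regulator of dopamine receptor signalling, -0.50 ± 0.18 (0.618). Thalamic and hypothalamic markers moved the same way, at -0.21 ± 0.13 over 18 genes (camera adjusted p = 0.0230, and adjusted p = 0.810 with an estimated correlation), with Zic1, a transcription factor of those regions, at -0.75 ± 0.24 (limma adjusted p = 0.590). Of the thalamic and hypothalamic genes 0 passed, also when adjusted over the list alone. Scores of this list were 0.19 ± 0.29 in sedentary SAMP8, -0.023 ± 0.18 in exercised SAMP8 and -0.17 ± 0.12 in SAMR1 (mean ± SD, n = 5 each). The call was lost without SAMP8 replicate 7 (-0.090, adjusted p = 0.317), without exercised replicate 15 (-0.17, 0.0943), and without the 2 arrays of lowest weight (-0.17, 0.0924).

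**Figure D2:**
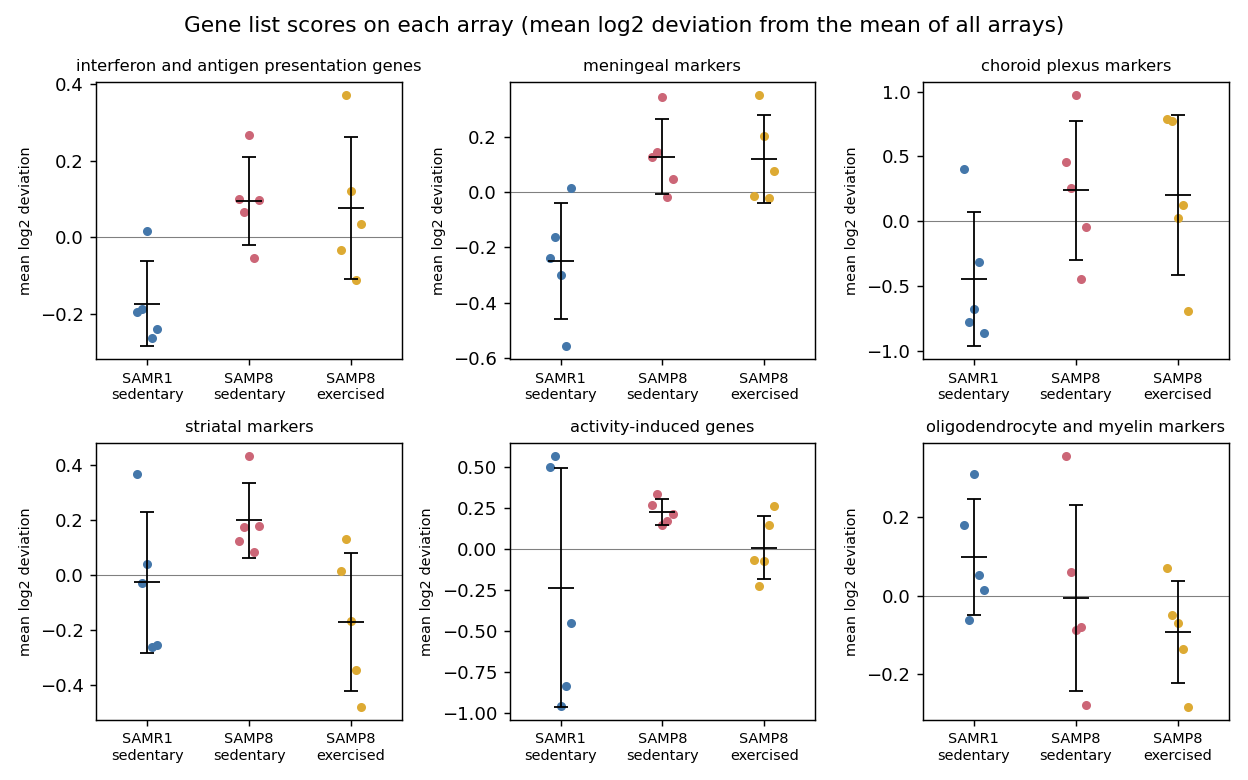
Score per array (vertical axis, mean log2 deviation of a list's genes from their mean over all arrays) of the interferon, meningeal, choroid plexus, striatal, activity-induced and oligodendrocyte lists in the 3 groups of 5 arrays, with points for arrays and bars for mean ± SD. Interferon and meningeal scores are higher on average in both SAMP8 groups (0.096 and 0.13 in sedentary SAMP8) than in SAMR1 (-0.17 and -0.25), and striatal scores are highest on average in sedentary SAMP8 (0.20).

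Ribosomal protein and oxidative phosphorylation lists had small negative shifts in exercised SAMP8, which depended on a few arrays. The ribosomal list had a mean of -0.074 ± 0.050, with 34 of 44 genes negative (camera adjusted p = 0.00127, and adjusted p = 0.810 with an estimated correlation), for example Rpl37 at -0.27 ± 0.12 and Rpl6 at -0.16 ± 0.08. The oxidative phosphorylation list had a mean of -0.059 ± 0.034, with 46 of 66 genes negative (camera adjusted p = 0.00159, and adjusted p = 0.810 with an estimated correlation), for example Uqcrb, a subunit of complex III, at -0.22 ± 0.08, while Cox5a of cytochrome c oxidase gave 0.18 ± 0.08. In both lists 0 genes passed over all genes or adjusted over the list alone. The exact permutation p of the score, before adjustment, was 0.214 for the ribosomal and 0.206 for the oxidative phosphorylation list. Oxidative phosphorylation scores were -0.12 and -0.10 on exercised replicates 11 and 14 and 0.029, 0.024 and 0.037 on replicates 12, 13 and 15, against -0.017 to 0.095 in sedentary SAMP8. Without exercised replicate 11 the mean of that list was -0.036 (camera adjusted p = 0.0389). Ribosomal scores were lowest on the same 2 arrays (-0.093 and -0.15), and the mean was -0.047 without exercised replicate 14 (0.0246) and -0.043 without sedentary replicate 6 (0.0434). With quantile normalization the means were -0.11 for the ribosomal and -0.093 for the oxidative phosphorylation list (4.91e-06 for both).

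Endothelial and mural markers had a mean of -0.077 ± 0.062 over 28 genes (camera adjusted p = 0.0414, and adjusted p = 0.810 with an estimated correlation). Of them 0 passed over all genes and 2 fell when adjusted over the list alone; smooth muscle actin, Acta2, had -0.53 ± 0.13 and the pericyte gene Rgs5 -0.46 ± 0.13. That call was lost without SAMP8 replicate 6 (-0.043, adjusted p = 0.214) or 7 (-0.068, 0.0628), exercised replicate 13 (-0.077, 0.0676), 14 (-0.055, 0.0851) or 15 (-0.070, 0.0943), the 2 arrays of lowest weight (0.105) and with the mean of all features (0.0509). Glucocorticoid-responsive genes had a mean of -0.10 ± 0.082 over 19 genes (camera adjusted p = 0.0414, and adjusted p = 0.810 with an estimated correlation), with Klf9, a hormone-induced transcription factor, at -0.36 ± 0.10 (limma adjusted p = 0.539) and 0 genes passing over all genes or adjusted over the list alone. It was lost without SAMP8 replicate 6 (-0.076, 0.0898) or 9 (-0.081, 0.221), exercised replicate 12 (-0.073, 0.110), 13 (-0.11, 0.0815) or 14 (-0.074, 0.0766), and with the mean of all features (0.0509).

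Neurotrophic and growth factors, 24 genes measured, had a mean of -0.026 after exercise (camera adjusted p = 0.173), with 0 passing over all genes or adjusted over the list alone. Sort1, the sorting receptor sortilin, had 0.36 ± 0.10 (limma adjusted p = 0.521, median of its other features -0.08) and Igf1r, the receptor of insulin-like growth factor, -0.30 ± 0.14 (0.704). Activity-induced genes had a mean of -0.22 (camera adjusted p = 0.0579), with Npas4, an activity-dependent transcription factor, at -0.65 ± 0.31 (limma adjusted p = 0.711); 0 passed over all genes and 1 fell when adjusted over the list alone.

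The remaining comparison set exercised SAMP8 against sedentary SAMR1 mice, which differ in both strain and exercise. The genes with the largest strain differences led again: Ccl19 was higher by 6.38 ± 0.11 (limma adjusted p = 6.36e-15), Adat2 by 2.56 ± 0.07 and Slc2a5 by 2.05 ± 0.10. Mal2, a membrane traffic protein, rose by 1.91 ± 0.11 (limma adjusted p = 5.19e-08). Gdpd5 fell by 3.66 ± 0.13 (7.29e-11), Prdm16 by 2.96 ± 0.15 (under the lower quartile on 4 of 5 exercised arrays) and Ppp1r1a by 2.62 ± 0.10. Rorb, a nuclear receptor of layer IV neurons, was the 1 gene among 20 cortical projection neuron markers that passed, also when adjusted over the list alone, and fell by 0.86 ± 0.14 (0.00237); the mean of its features was -0.49 (0.0166).

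In limma 698 genes passed, 460 higher and 238 lower in exercised SAMP8; with quantile normalization 610 passed, 341 higher and 269 lower. At an unadjusted p under 0.05 there were 2984 genes. In 576 of the 698, selected on these same arrays, the groups did not overlap. Over all genes the share was 5.80%, where chance gives 0.794%. Both contrasts with SAMR1 shared 382 genes in the same direction (232 higher and 150 lower) and 0 in opposite directions. Independent lists of those sizes would share 8.50 and 2.82 genes. Simulated groups with no effect against the same SAMR1 arrays shared 0.133 on average over 30 simulations. Those simulations called only 0.433 and 0.133 genes on average in the 2 contrasts, so a small overlap was fixed in advance. They cannot show how much sharing the common SAMR1 arrays create. With the SAMR1 arrays split between the contrasts, the median over 20 splits was 95.5 shared genes, from 82 to 127. The lists of these splits were shorter (medians of 229.5 and 207.5 genes), and independent lists of their sizes would share medians of 0.977 and 0.368.

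Interferon and antigen presentation genes had a mean of 0.25 ± 0.089 (camera adjusted p = 0.0178, and adjusted p = 0.810 with an estimated correlation). Of 31 genes 6 rose and 1 fell, and 11 rose and 1 fell when adjusted over the list alone. Oasl2 rose by 1.18 ± 0.13 (limma adjusted p = 4.78e-05), Oas1a by 0.82 ± 0.11 (0.000387) and Ifi27l2a by 1.66 ± 0.30 (0.00455). The member that fell was the MHC class I gene H2-D1 (-0.61 ± 0.12, 0.00892), chosen after its values were seen, which has close paralogs. The list's call was lost without exercised replicate 12 (0.18, adjusted p = 0.172) and without the dimmest 30% of genes (0.22, 0.163). Meningeal markers again moved with it, at 0.37 ± 0.11 (camera adjusted p = 0.000643, and adjusted p = 0.810 with an estimated correlation): 4 of 18 rose, 10 when adjusted over the list alone, among them Col1a1, a fibrillar collagen (0.79 ± 0.17), and Lum (0.65 ± 0.14).

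Oligodendrocyte and myelin markers were lower, at -0.19 ± 0.11 with 18 of 20 genes negative (camera adjusted p = 0.00131, and adjusted p = 0.810 with an estimated correlation). The 1 gene that fell, also when adjusted over the list alone, was Aspa, the aspartoacylase of myelin lipid synthesis (-0.69 ± 0.18, limma adjusted p = 0.0391). Aspa did not pass without SAMR1 replicate 1, 3, 4 or 5, sedentary SAMP8 replicate 8 or 9, or exercised replicate 13, 14 or 15 (-0.69 to -0.61, adjusted p up to 0.104). Ermn, a myelin cytoskeletal protein, had -0.39 ± 0.15 (0.158). Ribosomal protein genes had a mean of -0.061 ± 0.050 over 44 genes (camera adjusted p = 0.0255, and adjusted p = 0.810 with an estimated correlation), with 31 negative. That call was lost without SAMR1 replicate 1 (-0.049, adjusted p = 0.0653) or 3 (-0.040, 0.125), exercised replicate 14 (-0.034, 0.146), or the 2 arrays of lowest weight (-0.060, 0.0766), and the mean was -0.093 with quantile normalization (0.0106). Rpl13a alone passed over all genes (-0.36 ± 0.09, limma adjusted p = 0.0426), and 0 did when adjusted over the list alone. Rpl13a did not pass without SAMR1 replicate 1, 3 or 5, sedentary SAMP8 replicate 8, 9 or 10, or any 1 exercised array (replicates 11 to 15), where its adjusted p ran from 0.0508 to 0.0957.

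With the 3 scores as covariates, the added alternative, 46 genes passed between exercised SAMP8 and SAMR1, 44 of them among the 698. Rorb (-0.84, adjusted p = 0.628), Oasl2 (1.21, 0.101), Oas1a (1.07, 0.185), Ifi27l2a (1.5, 0.289), Col1a1 (0.71, 0.770), Lum (0.27, 0.861), Aspa (-0.91, 0.638) and Rpl13a (-0.44, 0.691) then did not pass in limma. Col1a1 and Lum are themselves in the meningeal score, so part of their loss can be built in.

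The last question was whether exercise moved the SAMP8 cortex toward SAMR1. Over the 497 genes that passed between the strains, the median absolute exercise difference was 0.098; these genes were selected on the sedentary SAMP8 arrays that the difference also uses, so this value alone tests no return. For Ccl19 the exercise difference was 0.16 ± 0.11 (limma adjusted p = 0.764), for Slc2a5 0.08 ± 0.10 (0.903), for Gdpd5 0.05 ± 0.13 (0.954) and for Ppp1r1a -0.01 ± 0.10 (0.989, other feature 0.12). Over all genes, the covariance of strain and exercise effects was -0.0194, against -0.0185 ± 0.0079 (mean ± SD) in 100 simulations with no effect that share the sedentary SAMP8 arrays; the difference was -0.000943. With those arrays split, the median covariance was -0.00352 (-0.0112 to 0.00315 over 20 splits), within the spread of simulations with no effect (-0.000519 ± 0.00867). Those simulations held no strain effect either, so their spread leaves out what a real strain difference adds. The smallest return that could have been seen was not established. Among genes called between the strains on 1 part of the arrays (a median of 221.5 genes, from 107 to 315), 46.5% had an exercise difference toward SAMR1 on the other part (40.8% to 51.9%). A return toward SAMR1 over these genes as a set was not detected with 5 arrays per group.

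**Figure D3:**
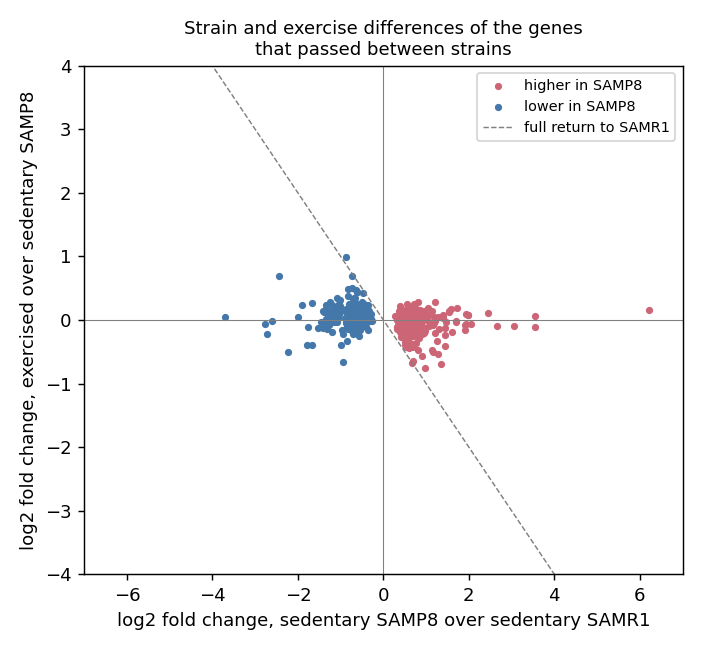
Strain difference (horizontal axis, log2, sedentary SAMP8 minus SAMR1) against exercise difference (vertical axis, log2, exercised minus sedentary SAMP8) of the 497 genes that passed between the strains, 1 point per gene, with a dashed line where exercise would return a gene to its SAMR1 level. Points lie along 0 on the vertical axis (median absolute value 0.098, against 0.65 on the horizontal axis); both axes use the sedentary SAMP8 arrays.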

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

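The tests of 1 array, of meningeal tissue and of microglia were chosen only after the results they bear on were seen. In 150 groups of 5 arrays (scores of the 13 lists called in any comparison and the values of 37 genes), 8 had 1 array far from the other 4, where chance gives about 7.5.

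The striatal score of sedentary SAMP8 replicate 8 was 0.4328, against 0.082 to 0.178 on the other arrays of its group. The list's lower mean in exercised SAMP8 does not rest on 1 array alone: with exercised replicate 15 left out, which shrinks it most, the mean was -0.2897 against -0.37 over all arrays. Different amounts of striatal tissue in the dissected cortex are a candidate explanation, since over the 16 genes the exercise difference was larger where a gene varied more with the other striatal genes within groups. Pearson's r was -0.6433 across genes (Spearman -0.574, permutation p = 0.0055, r = -0.551 without the 2 genes farthest from the median coupling), and genes are not independent replicates. An effect of exercise on these transcripts stays open, as the design gives no array with known striatal content.

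The interferon score of SAMR1 replicate 3 was 0.01761, against -0.26 to -0.19 on the other SAMR1 arrays. More microglia in SAMP8 samples would not account for all of the list's shift, if these markers follow microglia: over all 31 genes it exceeded that of the microglia markers by 0.22, with a lower 95% bound of 0.03695. The 7 list genes that passed between the sedentary strains had a mean difference of 0.769 (95% interval 0.520 to 1.02), a size that choosing genes by p can raise. With the meningeal score as a covariate the mean difference of the 7 genes was 0.4769 (0.222 to 0.731), so more meningeal tissue may account for part of it and, with the interval reaching under 50% of the unadjusted value, how large a part stays open. A difference between the strains in interferon signalling also stays open and was not tested by other means.

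The remaining lone arrays are given as values. The oxidative phosphorylation score of SAMR1 replicate 5 was -0.05804, against -0.0046 to 0.013. Among genes, log2 intensities were 7.225 for Rpusd4 in SAMR1 replicate 5 (others 7.67 to 7.83), 10.63 for Pramel39 in SAMR1 replicate 4 (9.39 to 9.61) and 11.79 for Dcaf12l1 in sedentary SAMP8 replicate 6 (11.88 to 11.91). In exercised SAMP8 they were 8.429 for Deptor in replicate 11 (7.85 to 7.96) and 7.819 for Peg3 in replicate 15 (8.86 to 9.18). Features without a single gene symbol, which the gene comparisons do not use, also differed between the sedentary strains: 157 of 6511 passed an adjusted p of 0.05 in limma (81 higher and 76 lower), beside 744 of 27968 features with 1 symbol.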

How the results depend on the processing

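The covariate fit and the fit without the 2 arrays of lowest weight were chosen only after the data were seen; all other alternatives, the comparisons, lists and naming rule were fixed before the data were examined. No paired analysis was possible because the replicate numbers 1 to 15 do not repeat between groups. Between sedentary SAMP8 and SAMR1, 497 genes became 272 at an adjusted p of 0.01 (by construction) and 139 with the 3 scores as covariates (the cause was not tested); leaving out 1 array gave 386 (SAMR1 replicate 5) to 516 (SAMR1 replicate 2), and leaving out SAMR1 replicate 2 with exercised replicate 15 gave 525. The exercise count was 0 under each alternative except 3 without exercised replicate 12 (range 0 to 3). Between exercised SAMP8 and SAMR1, 698 became 312 at 0.01 and 447 at a log2 difference of at least 0.5 (both by construction), 46 with the covariates (the cause was not tested), 483 (SAMR1 replicate 5) to 848 (SAMR1 replicate 2) with 1 array left out, and 611 without the 2 arrays. The 6, 6 and 4 lists called by camera fell to 0 with an estimated correlation and 0 with fry in each comparison; with 1 array left out they numbered 5 to 8, 4 to 9 and 3 to 6. The split covariance of strain and exercise effects ran from -0.00937 to 0.00294 with 1 array left out, and the share of genes moving toward SAMR1 from 42.6% to 50.7%. Of the gene results that the naming rule gave and that passed, 53 between the sedentary strains and 58 between exercised SAMP8 and SAMR1, leaving out some 1 array ended 8 and 12, the covariates 26 and 38, and the mean of all features 5 and 9. Named results were picked for large changes or small p, so they do not stand for all calls. Of the 497 genes, 371 passed again without SAMR1 replicate 5 and 423 without SAMR1 replicate 2. No gene or list result that passed changed sign under the alternatives run. For genes, several alternatives could not show such a change, since they keep the chosen feature and its difference. These were no collapse to genes, the trended and robust prior, only the 2 groups compared and leaving out dim genes. Other features of a gene can have the opposite sign, as for Chrna4. For gene results that did not pass, signs were compared only where an alternative made them pass. With the covariates, some sizes shrank and others grew between exercised SAMP8 and SAMR1. Lum, itself in the meningeal score, went from 0.65 to 0.27. Gstm2, in none of the 3 scores, went from 0.91 to 0.59, and Eif4ebp1 from -0.63 to -0.96. None of these genes then passed in limma. The lower counts alone thus do not show that tissue content explains the differences. Signal over background was not given in the sources used here, so dim features are limited by an unknown floor.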

Other observations

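Of the tests reported here, that of single features was chosen only after its result was seen, and so was the count of splits for the exercise comparison. Of genes outside the fixed interferon list, 4 that are known to be induced by interferon were chosen after their values were seen, because they were higher in sedentary SAMP8 than in SAMR1; they were not tested as a group. Eif2ak2, the antiviral kinase PKR, had 1.09 ± 0.14 (SE, n = 5 each, limma adjusted p = 0.000175), Ifi204, a DNA-sensing family member, 0.60 ± 0.11 (0.00526), Trim30a 0.63 ± 0.14 (0.0161) and Lgals3bp 0.73 ± 0.17 (0.0246). The SAMR1 means of Ifi204 (5.62) and Trim30a (5.92) lay under the lower quartile of log2 intensity, 6.17. Their exercise differences were -0.07 ± 0.14, 0.17 ± 0.11, -0.17 ± 0.14 and 0.08 ± 0.17.

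Among senescence and p53 genes, Mdm2, the ubiquitin ligase of p53, was higher in sedentary SAMP8 by 0.43 ± 0.09 (limma adjusted p = 0.00947, and 0.43 at an adjusted p of 0.354 with the 3 scores as covariates, an alternative added after the data were seen, which left the size and widened the standard error to 0.14). The 23 genes had a mean of 0.17 (camera adjusted p = 0.0766), with 2 rising over all genes and 5 rising and 0 falling when adjusted over the list alone. Microglia markers had a mean of 0.044 (camera adjusted p = 0.717), and the 30 amyloid and tau genes -0.014 (0.363), with 0 passing in either list. App, the amyloid precursor and a gene long studied in SAMP8, had -0.05 ± 0.09 between the sedentary strains (limma adjusted p = 0.869) and 0.22 ± 0.09 with exercise (0.682). Bdnf, the neurotrophin most often linked to exercise, had 0.23 ± 0.14 with exercise (limma adjusted p = 0.764). App and Bdnf were chosen after their values were seen.

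The strain differences had neighbouring genes among them more often than random draws, though most had no such neighbour. Of the 495 called genes with a known place, 111 had another called gene as the next tested gene on the chromosome, against a median of 29 and a highest of 62 in 10000 random draws (permutation p = 1e-04, the smallest the draws can give), and 95 against 26 when neighbours with the same first 3 letters were left out. The longest of 9 runs of at least 3 genes held Rpp25l (1.13), Dctn3 (1.53), Galt (-0.56), Ccl27a (0.91), Gm3893 (3.54) and Ccl19 (6.22), so inherited blocks that differ between the strains may carry part of the strain signature, including copy-number differences, which were not tested. A fault or variant at the chosen feature alone would not account for all strain calls, if the features of a gene do not overlap. Probe sequences were not used, so overlap was not checked. Of 68 called genes with a bright second feature, 57.35% (39 genes, 95% interval 44.8% to 69.3%) showed the same direction at an unadjusted p under 0.05, 5 the opposite and 24 neither. The other called genes were not covered. The median ratio of the second feature's log2 difference to that of the chosen feature was 0.581, so sizes given on the chosen feature may be larger than another feature of the gene would give. For both contrasts with SAMR1, 1 of 100 splits of the arrays, the real one, gave as many genes (497 against a highest other of 18, and 698 against 0). A chance division of these arrays is thus unlikely to give such counts. The splits cannot test for pooled or repeated material or for slides. For exercise the real count was 0, which any split reaches (100 of 100, highest other 1), so the splits decide nothing about chance there.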
